A study of Mus musculus with 6 samples.

How the data were processed

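Messenger RNA was sequenced from inguinal white adipose tissue (iWAT), the subcutaneous fat pad of the mouse in which cold induces heat-producing beige adipocytes. Per the labels' protocols, total RNA was extracted with TRIzol, purified on a column, and made into stranded poly(A)-selected Illumina libraries. The 6 libraries form 2 groups of 3. Atf4AKO mice carried the floxed Atf4 gene with Cre recombinase under the adiponectin promoter, and Atf4WT mice carried the floxed gene without Cre. Cre thus went with the group in every library. An effect of Cre, or of DNA inherited with it, cannot be told apart from loss of Atf4. All mice were kept at 22 °C and then at 5 °C for 12 h before the tissue was frozen. Groups and replicate numbers were taken from the sample titles, and the columns of the table were matched to samples by the sample descriptions. The labels do not state whether each library is 1 animal or a pool, nor litter or sex, so p-values measure the spread between these libraries.

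The deposited table holds FPKM (fragments per kilobase of transcript and per 1e6 mapped fragments), 1 value per gene symbol and library for 23997 symbols. Per the submitters' processing notes the genome build was mm10. The aligner, the quantifier and the annotation are not given in the sources used here. FPKM depends on the transcript length used, on how reads shared by similar genes were assigned, and on the total of each library, so a few very abundant transcripts can lower all others. The sums of FPKM ran from 524158 in Atf4WT 1 to 717778 in Atf4AKO 2, and the 10 highest genes held between 15.3% and 19.5% of each sum. Whether reads were counted by strand is not given, so overlapping and antisense genes may not be separated, and genes with near-identical copies are uncertain. FPKM does not give the total of reads. Relative depth was read from genes under 0.15 FPKM, where values move in steps of whole reads. In pairs of libraries, between 80.3% and 88.3% of the ratios of such genes lay within 0.02 (log2) of the modal ratio times a ratio of whole numbers up to 6. From the modal ratios, Atf4WT 1 was the deepest library, 1.28 times as deep as Atf4AKO 3, the shallowest. Absolute depth is unknown, so no counting interval or detection limit is given, and a gene at 0 is called listed at 0.

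The values were analysed as log2(FPKM + 1). Genes with a mean of at least 0.5 FPKM over the 6 libraries were kept, which left 12818. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend), with no covariate, and p-values were adjusted by Benjamini-Hochberg over all tested genes with a threshold of 0.05. A count model was not used because the values are not counts. A log2 change is the difference of group means on the log2(FPKM + 1) scale, Atf4AKO minus Atf4WT, and it understates the change of genes of low FPKM. Ratios are ratios of mean FPKM. Single genes were also compared by an exact two-sided permutation test, whose smallest p with 3 against 3 libraries is 0.1.

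The 38 lists of pathway genes and cell type markers were fixed before the data were examined. Of their 839 entries 22 had no row in the table, 3 were found under another symbol through RefSeq synonyms, and 36 lists with at least 5 tested members were tested with camera (preset correlation 0.01) on the same values, adjusted over the lists. The 13 mitochondrially encoded transcripts had no row and were not analysed here, and the sex-linked list had too few tested members. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were run beside it. Named genes also followed a rule fixed before the data were examined. The rule takes Atf4 and Mthfd2, then up to 12 genes a direction that pass with no overlap between groups. Where fewer pass it adds up to 8 genes a direction of smallest p as values only. It also takes up to 4 members of each list described, and passing members of the first 6 lists. Predicted genes are left out among passing genes. Other genes are said to have been chosen after their values were seen. The values of 1 list member are not reported here.

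The procedure was tested on simulated data for this comparison, with 12818 genes drawn around the real means and spreads and 200 genes changed in each of 10 runs. It recovered 54.2% of genes changed 2-fold, 88.6% of those changed 4-fold, 94.6% of those changed 8-fold and 97.4% of those changed 16-fold, with a mean of 13.9 false calls a run. A planted list was called in 10 of 10 runs, and 0 of 200 unchanged lists were called. The simulated genes were drawn independently of each other, so these runs do not measure false list calls among genes that move together. When the real libraries were split with the groups mixed, the same list test called 11 to 23 lists. The recovery of genes holds for 200 changed genes a run, and fewer changed genes would make the adjusted threshold harder to pass. The fold sizes were shifts of the analysed log2 values, so at low FPKM they stand for larger folds of FPKM. Recovery was not split by FPKM, so these percentages need not hold for genes near the expression filter.

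Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter, a mean filter of 2 FPKM, median-of-ratios scaling, quantile normalization, rescaling to equal sums (TPM), robust eBayes, eBayes without trend, weights per library, the replicate number as a block, each library left out, an adjusted p of 0.1, a 1.5-fold minimum, and the other list tests. Added after the data were seen were a fit without Atf4AKO 1 and 2, in which Atf4AKO 3 is the only knockout library and is assumed to vary like Atf4WT, and fits with the mean level of the skeletal muscle or the epithelial list as a covariate. Gene positions are from RefSeq on GRCm38, the assembly of mm10, which placed 99.7% of the tested genes, and strands are from GENCODE. Depth, positions and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.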

Results

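Gene expression in iWAT was compared between 3 libraries of mice lacking Atf4 in adipocytes (Atf4AKO) and 3 libraries of floxed mice without Cre (Atf4WT), all after 12 h at 5 °C. The comparison asks how the transcription factor ATF4, the effector of the integrated stress response, acts in adipocytes during cold, and the series title names Mthfd2, a mitochondrial enzyme of folate metabolism, as its target in browning. All mice were exposed to cold, so the libraries give no cold response, only the difference between genotypes in the cold. Between 15939 and 16504 genes had a value above 0 in a library, and relative depth ran from 0.932 to 1.19 of the mean.

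Atf4 was 299 ± 36.2 FPKM in Atf4WT and 135 ± 19.4 FPKM in Atf4AKO (mean ± SD, n = 3 each), 2.21 times as high in Atf4WT. Every Atf4AKO library, the highest at 152.1 FPKM, lay below every Atf4WT library, the lowest at 257.6 FPKM, so the targeted gene went with the label of each library. The log2 change was -1.14 (SE 0.16, 95% interval -1.52 to -0.76). It did not pass over all genes (limma adjusted p = 0.49), and the exact two-sided permutation p was 0.1, the smallest this design allows. Atf4 lies on chromosome 15 from 80255184 to 80257545 on the plus strand (GRCm38). iWAT also holds cells other than adipocytes, and these values are of the whole pad.

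Mthfd2 did not differ detectably between the groups. It was 3.77 ± 1.30 FPKM in Atf4WT and 3.81 ± 1.58 FPKM in Atf4AKO (mean ± SD, n = 3 each). The log2 change was -0.01 (SE 0.30), with a 95% interval from -0.72 to 0.70, which spans a fall of 1.65-fold to a rise of 1.63-fold, and the limma adjusted p was 0.993. The exact permutation p was 1. The libraries of the groups overlapped, from 2.63 to 5.20 FPKM in Atf4WT and from 2.34 to 5.48 FPKM in Atf4AKO. The difference turned to 0.20 without Atf4WT 2 and to 0.23 without Atf4AKO 3, but was -0.19 without Atf4WT 1 and -0.25 without Atf4AKO 1. With the muscle score covariate, added after the data were seen, it was -0.31. The values are of the whole pad, so a change confined to adipocytes may be masked. Mthfd2 lies on chromosome 6 from 83305704 to 83326011 on the minus strand (GRCm38).

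**Figure D1:**
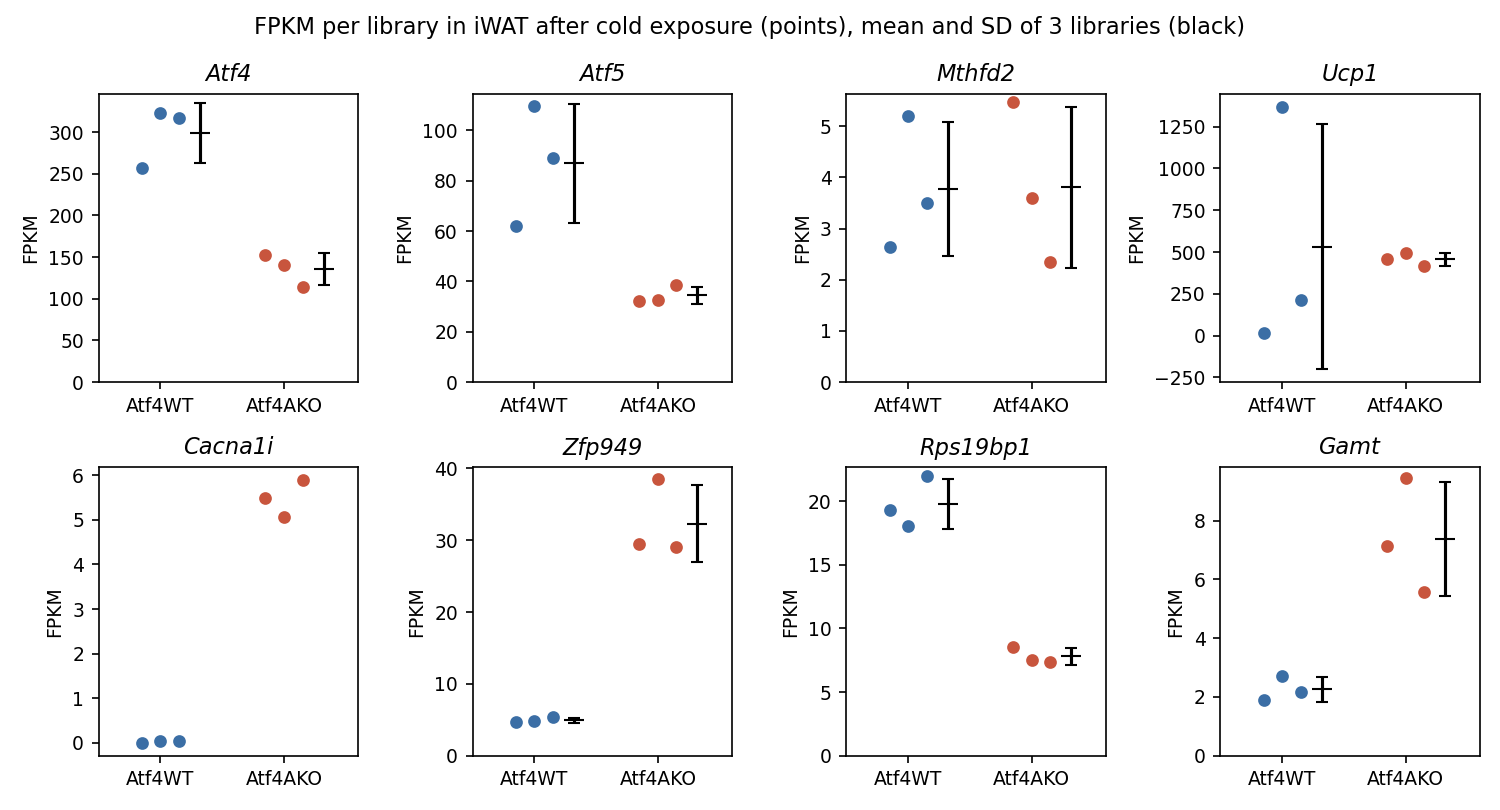
FPKM (vertical axes, linear) of 8 genes in each library, with Atf4WT in blue and Atf4AKO in red; black marks are the mean and SD of 3 libraries, left out for Cacna1i, which 1 Atf4WT library lists at 0. Atf4, Atf5 and Rps19bp1 are lower in every Atf4AKO library than in every Atf4WT library, Cacna1i, Zfp949 and Gamt are higher, and Mthfd2 and Ucp1 overlap; the panel of Ucp1, with values from 15.5 to 1370, was chosen after the values were seen.

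Cacna1i and Zfp949 were the 2 genes of 12818 that rose in Atf4AKO past the threshold. Cacna1i, a T-type voltage-gated calcium channel, was listed at 0, 0.0407 and 0.0268 FPKM in the 3 Atf4WT libraries and at 5.49, 5.06 and 5.90 FPKM in the Atf4AKO libraries. Its log2 change was 2.66 (SE 0.12, limma adjusted p = 0.00306), a size set by the pseudocount of 1, since it was 3.52 with 0.5 and 5.52 with 0.1. Zfp949, a zinc finger gene, rose from 4.92 ± 0.375 to 32.3 ± 5.37 FPKM (mean ± SD, n = 3 each), a ratio of 6.57 and a log2 change of 2.48 (SE 0.14, limma adjusted p = 0.0067). Cacna1i lies on chromosome 15 from 80287238 to 80398292 on the plus strand, 29.7 kb downstream of Atf4, and Zfp949 lies on chromosome 9 from 88548020 to 88571086 on the plus strand (GRCm38). No gene fell past the threshold: limma called 0 genes lower, while 1276 genes had an unadjusted p under 0.05 (646 higher, 630 lower), where 641 would be expected by chance. Splits of the libraries that mixed the groups gave from 81 to 1339 genes with an unadjusted p under 0.05 by limma, so this excess cannot be credited to genotype. The count was 500 without Atf4AKO 2 and 2609 without Atf4AKO 3. In 1052 genes all Atf4AKO libraries lay above all Atf4WT libraries and in 1069 all lay below, 16.6% of the genes tested where chance gives 10%. Genes that move together let this share vary widely between splits, and it was not counted in the mixed splits. It cannot be credited to genotype either. The count of 2 higher genes became 0 without Atf4AKO 1, where the log2 changes of Cacna1i (2.66) and Zfp949 (2.54) each had a limma adjusted p of 0.0506. It became 1 without Atf4WT 1, 1 without Atf4WT 2 and 3 without Atf4WT 3, and 2 genes were lower without Atf4WT 2. With the replicate number as a block the count of higher genes was 0 (limma adjusted p = 0.156 for Cacna1i and for Zfp949). With the muscle or the epithelial score covariate, added after the data were seen, Zfp949 was not called (limma adjusted p = 0.0708 and 0.0549), whereas Cacna1i was.

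The genes of next smallest p did not pass and are given as values, in FPKM as mean ± SD with n = 3 in each group. In all of them the groups did not overlap. Higher in Atf4AKO were Ptx3, a secreted pentraxin (12.7 ± 1.27 and 32.3 ± 6.18), Rgs1, a regulator of G-protein signalling (3.90 ± 0.436 and 16.9 ± 6.88), and the chemokine gene Ccl7 (10.7 ± 0.755 and 26.035 ± 7.13). So were Gamt, the enzyme of the last step of creatine synthesis (2.26 ± 0.423 and 7.38 ± 1.95), the metalloprotease gene Adamts15 (40.2 ± 1.29 and 65.1 ± 6.49), and Bmper, a binder of bone morphogenetic proteins (12.4 ± 1.80 and 26.9 ± 6.23). A730098P11Rik (0.532 ± 0.0650 and 3.17 ± 0.406), a transcribed pseudogene by RefSeq, and H2-L (38.2 ± 1.85 and 64.5 ± 3.94), a class I histocompatibility gene, have near-identical relatives, so their values are uncertain. Lower in Atf4AKO was Rps19bp1 (19.8 ± 1.99 in Atf4WT and 7.80 ± 0.655 in Atf4AKO, limma adjusted p = 0.0903), whose nearer edge lies 3.1 kb past the end of Atf4, on the opposite strand. Also lower were Atf5, a transcription factor of the same family as Atf4 (86.9 ± 23.8 and 34.5 ± 3.51), Coa4, a cytochrome c oxidase assembly factor (4.11 ± 0.162 and 1.96 ± 0.370), and the retinol dehydrogenase gene Rdh5 (2.38 ± 0.410 and 0.866 ± 0.161). C1qtnf9, a secreted protein related to adiponectin (14.0 ± 2.21 and 7.38 ± 1.13), the peroxisomal protease gene Tysnd1 (55.9 ± 2.37 and 36.4 ± 3.91) and Smco4 (5.82 ± 0.860 and 3.26 ± 0.226) were lower as well.

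**Figure D2:**
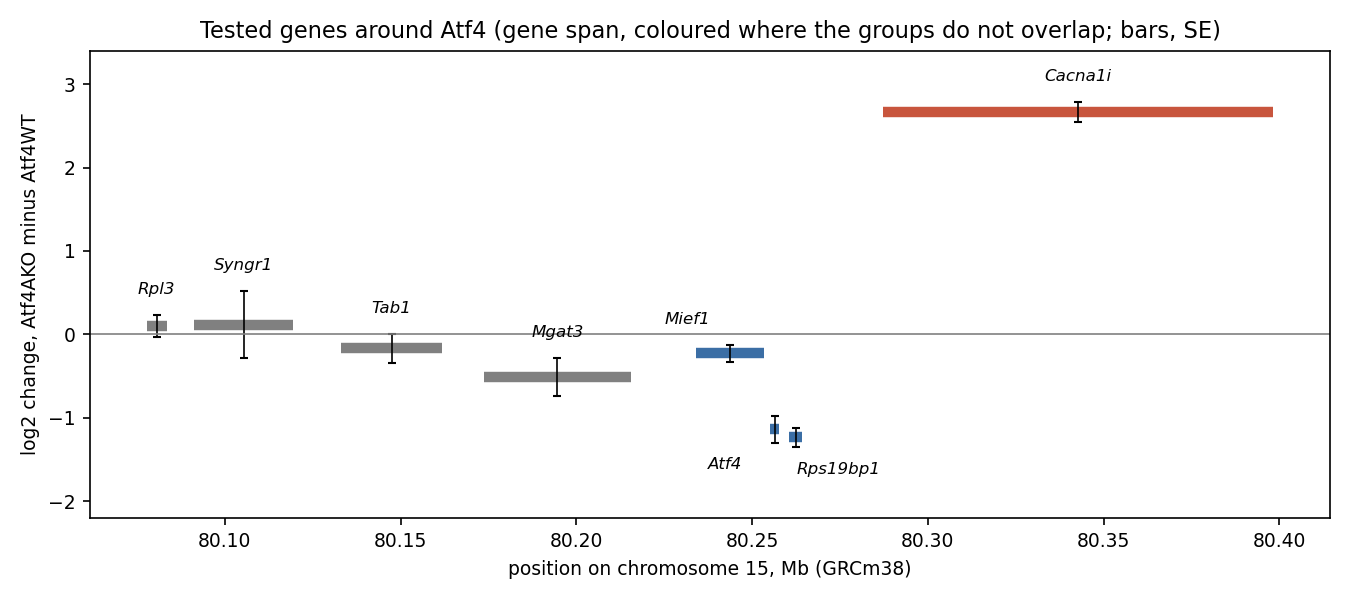
Log2 change (vertical axis, Atf4AKO minus Atf4WT, on the log2(FPKM + 1) scale) of tested genes along chromosome 15 (horizontal axis, Mb on GRCm38); thick lines are gene spans, red where all Atf4AKO libraries were above all Atf4WT libraries, blue where all were below and grey where they overlapped, and thin bars are SE. Rps19bp1 has a log2 change of -1.24 and Cacna1i of 2.66, next to Atf4 at -1.14.

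Cytosolic aminoacyl-tRNA synthetases, which load amino acids on transfer RNA, fell as a list in Atf4AKO. The list also holds Xpot, an exporter of transfer RNA. Of 21 members 17 had a negative log2 change, with a list median of -0.21, and in 8 all Atf4AKO libraries lay below all Atf4WT libraries (camera adjusted p = 0.00084, and adjusted p = 0.767 with an estimated correlation). No single member passed, over all genes or adjusted over the list alone. Mars was 15.2 ± 1.31 and 10.9 ± 0.965 FPKM, Yars 15.1 ± 2.53 and 10.4 ± 0.287 FPKM, Cars 12.0 ± 2.59 and 7.42 ± 1.09 FPKM, and Sars 37.0 ± 3.50 and 28.7 ± 1.69 FPKM in Atf4WT and Atf4AKO (mean ± SD, n = 3 each).

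The other lists tied to ATF4 were not called. Among 19 integrated stress response targets 13 had a positive and 6 a negative log2 change (camera adjusted p = 0.102, and 0.906 as the adjusted p with an estimated correlation). Atf5 was the 1 member that passed adjusted over the list alone (limma adjusted p = 0.015), and no member passed over all genes. Members lay on both sides: Cebpg was 30.4 ± 4.25 in Atf4WT and 19.1 ± 4.73 FPKM in Atf4AKO, whereas Atf3 was 13.0 ± 1.46 and 23.3 ± 6.01 FPKM, and Sesn2 was 43.7 ± 7.91 and 80.0 ± 26.99 FPKM (mean ± SD, n = 3 each). Serine and one-carbon folate metabolism had 11 members up and 11 down in sign (camera adjusted p = 0.8). Its members of smallest p were Mtfmt at 6.64 ± 0.763 and 4.10 ± 1.03 FPKM, Mthfs at 2.67 ± 0.111 and 4.38 ± 1.11 FPKM, Fpgs at 7.97 ± 0.802 and 6.09 ± 0.697 FPKM, and Phgdh, the first enzyme of serine synthesis, at 21.0 ± 1.6 and 36.8 ± 14.6 FPKM. Amino acid synthesis and transport had 8 members up and 9 down in sign (camera adjusted p = 0.878), with Asns, asparagine synthetase, at 37.7 ± 7.52 and 24.8 ± 2.82 FPKM and Cbs at 34.5 ± 7.35 and 19.5 ± 8.42 FPKM, but the transaminase gene Got1 at 30.9 ± 10.5 and 49.1 ± 1.53 FPKM and Glul, glutamine synthetase, at 2072 ± 187.4 and 2783 ± 515.9 FPKM. Purine and pyrimidine synthesis had 16 of 17 members negative in sign with a median of -0.12 (camera adjusted p = 0.06), and the list was called lower without Atf4WT 2 (adjusted p = 0.00512). With all libraries its adjusted p with an estimated correlation was 0.906, and it was called in 2 of 20 alternatives. No member of these 3 lists passed, over all genes or adjusted over the list alone. The stress response list was called higher without Atf4WT 2 (adjusted p = 0.0197), after rescaling to equal sums (adjusted p = 0.00869) and with Atf4AKO 3 as the only knockout library (adjusted p = 0.0327), 3 of 20 alternatives.

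Thermogenic and beige adipocyte genes were not called (19 of 27 members positive in sign, camera adjusted p = 0.261), and no member passed over all genes or adjusted over the list alone. Ppargc1a, a coactivator of mitochondrial genes, was 5.78 ± 2.52 FPKM in Atf4WT and 14.6 ± 8.17 FPKM in Atf4AKO, and Dio2, which activates thyroid hormone, was 7.11 ± 8.93 and 9.92 ± 1.97 FPKM (mean ± SD, n = 3 each). Ucp1, the uncoupling protein of thermogenic fat, was named after its values were seen. It was 15.5, 1370 and 211 FPKM in Atf4WT and 456, 497 and 415 FPKM in Atf4AKO. Its log2 change of 1.44 had a 95% interval from -2.07 to 4.94, so the spread within Atf4WT leaves a large difference either way undetected. The level of the list in single libraries ran from -1.22 in Atf4WT 1 to 0.95 in Atf4WT 2, wider than the 3 Atf4AKO libraries, which lay between 0.16 and 0.18 (log2, relative to the mean of the 6 libraries). Without Atf4WT 2 the list was called higher in Atf4AKO (median 0.60, adjusted p = 2.16e-07), but with all libraries its adjusted p was 0.906 with an estimated correlation and 0.901 by fry. It was also called higher after rescaling to equal sums (adjusted p = 0.0312), where its median was -0.02, and in no other of 20 alternatives.

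Immediate early genes and inflammatory genes rose as lists in Atf4AKO. Of 21 immediate early genes 17 were positive in sign with a median log2 change of 0.51, and in 12 all Atf4AKO libraries lay above all Atf4WT libraries (camera adjusted p = 1.32e-07, and adjusted p = 0.659 with an estimated correlation). Adjusted over the list alone 9 members passed, and over all genes 0. Btg2 was 98.4 ± 12.4 and 245.5 ± 114.7 FPKM, Dusp1, a phosphatase of MAP kinases, 157 ± 1.11 and 240.4 ± 40.9 FPKM, and Klf4 72.2 ± 2.62 and 100.05 ± 10.2 FPKM in Atf4WT and Atf4AKO (mean ± SD, n = 3 each). Of 17 inflammatory cytokines and chemokines 15 were positive in sign with a median of 0.65 (camera adjusted p = 3.64e-07, and adjusted p = 0.659 with an estimated correlation). Adjusted over the list alone 7 passed, and over all genes 0. Cxcl2, which attracts neutrophils, was 3.85 ± 1.51 and 30.5 ± 21.9 FPKM, and Ccl3 was 2.14 ± 0.468 and 6.49 ± 2.88 FPKM. The level of the inflammatory list was 1.00 in Atf4AKO 1 against 0.21 and 0.05 in Atf4AKO 2 and 3.

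Matrix genes and markers of macrophages and fibroblasts also rose as lists, and here Atf4AKO 1 stood apart. Extracellular matrix genes were positive in sign in 23 of 24 (median 0.83, camera adjusted p = 5.33e-08), fibroblast and preadipocyte markers in 15 of 19 (median 0.49, adjusted p = 0.00128), and macrophage markers in 17 of 17 (median 1.36, adjusted p = 9.2e-06). Each has an adjusted p of 0.906 with an estimated correlation, and no member passed over all genes or adjusted over the list alone. Lum, a collagen-binding proteoglycan in both the matrix and the fibroblast list, was 15.5 ± 4.20 and 41.4 ± 19.9 FPKM, and Sparc was 635 ± 71.2 and 958 ± 154.9 FPKM (mean ± SD, n = 3 each). C1qb, a complement gene of macrophages, was 86.0 ± 39.6 and 309.7 ± 244.9 FPKM, and Mrc1 was 18.0 ± 7.80 and 43.9 ± 24.8 FPKM. The level of the macrophage list was 1.93 in Atf4AKO 1, 0.22 in Atf4AKO 2 and -0.38 in Atf4AKO 3, and between -1.05 and -0.07 in Atf4WT. Without Atf4AKO 1 its median was 0.50 (adjusted p = 0.00114), that of the matrix list was 0.52 (adjusted p = 7.12e-07), and that of the fibroblast list was 0.22 (adjusted p = 0.0122). The macrophage list (median 0.22, adjusted p = 0.0582) and the fibroblast list (median 0.07, adjusted p = 0.142) were not called without Atf4AKO 1 and 2, a fit added after the data were seen in which Atf4AKO 3 stands alone and is assumed to vary like Atf4WT.

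Skeletal muscle markers differed between libraries more than between groups. The list was called higher in Atf4AKO, with 20 of 20 members positive in sign and a median of 2.94 (camera adjusted p = 0.000153, and adjusted p = 0.906 with an estimated correlation), and no member passed. Its level was 2.63 in Atf4AKO 1, 3.88 in Atf4AKO 2 and 1.09 in Atf4WT 2, against -2.70 in Atf4AKO 3, -2.27 in Atf4WT 1 and -2.63 in Atf4WT 3. Eno3, the muscle enolase, was 12.7 ± 13.6 and 103.4 ± 109.1 FPKM (mean ± SD, n = 3 each). Without Atf4AKO 1 and 2, which leaves Atf4AKO 3 alone against 3 Atf4WT libraries, the median was -1.84 and the list test turned (adjusted p = 0.00131), a value of 1 library that shows no direction for the genotype. Mammary and skin epithelial markers were called lower in Atf4AKO (15 of 18 members negative in sign, median -1.27, camera adjusted p = 0.0378, and adjusted p = 0.906 with an estimated correlation), and no member passed over all genes or adjusted over the list alone. Their level was 2.42 in Atf4WT 1, 0.74 in Atf4WT 2 and 0.65 in Atf4AKO 3, and between -1.52 and -0.83 in the other libraries. Without Atf4WT 1 the list was not called (adjusted p = 0.789), nor without Atf4AKO 1 (adjusted p = 0.352), and it was called in 9 of 20 alternatives, with adjusted p up to 0.955 (with Atf4AKO 3 as the only knockout library, median 0.10).

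**Figure D3:**
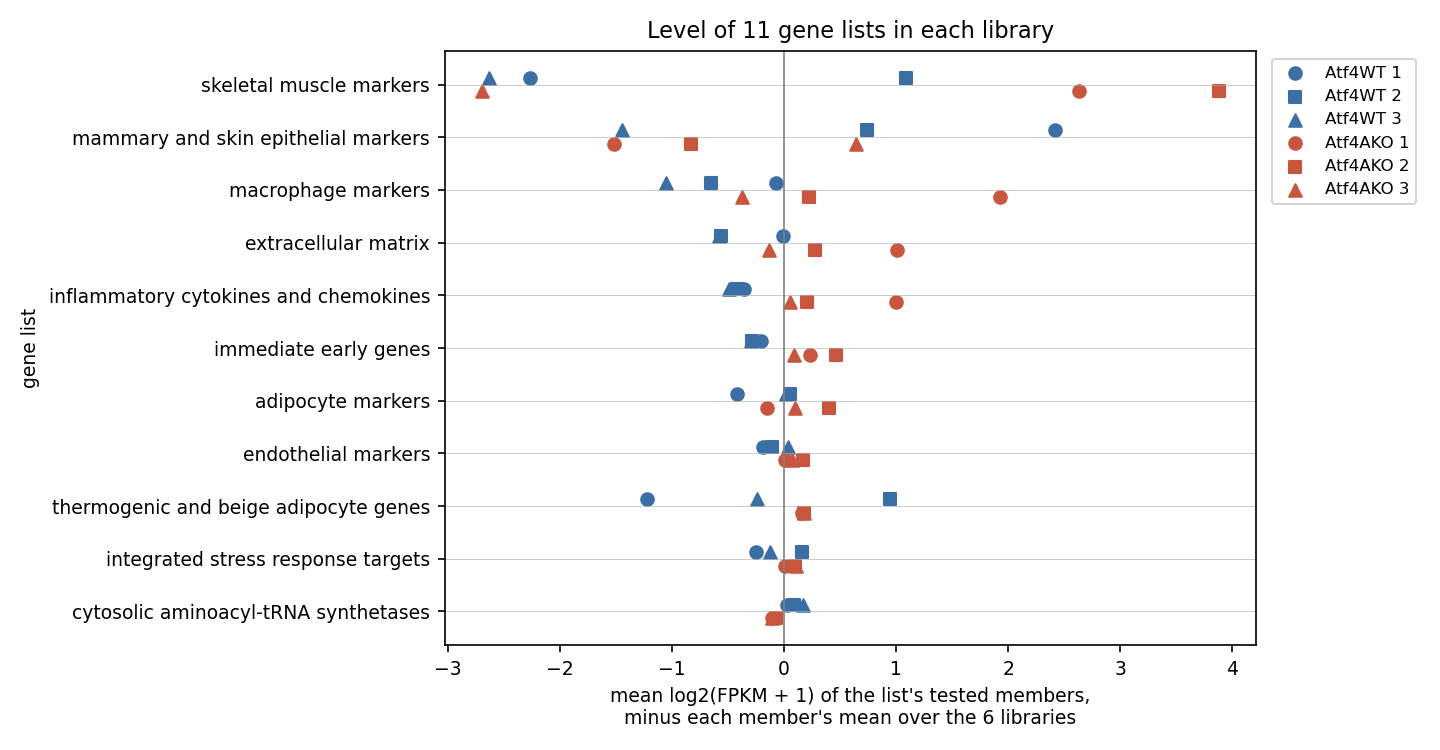
Level of 11 gene lists (vertical axis) in each library: the mean log2(FPKM + 1) of the tested members relative to each member's mean over the 6 libraries (horizontal axis), with Atf4WT in blue, Atf4AKO in red and a symbol per replicate number. Muscle markers run from -2.70 to 3.88, and the inflammatory and immediate early lists are higher in all Atf4AKO libraries than in any Atf4WT library.

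Energy metabolism lists called higher in Atf4AKO had small medians, in a comparison in which skeletal muscle markers were at 2.63 and 3.88 in Atf4AKO 1 and 2. They were respiratory chain subunits (72 of 75 positive in sign, median 0.17, camera adjusted p = 0.0152), the tricarboxylic acid cycle (21 of 22, median 0.24, adjusted p = 0.0487), and glycolysis and hypoxia response (18 of 21, median 0.24, adjusted p = 0.00166). Adipocyte markers (14 of 20, median 0.24, adjusted p = 0.0427), cytosolic ribosomal proteins (49 of 52, median 0.10, adjusted p = 0.00668), proliferation (15 of 17, median 0.19, adjusted p = 0.0427) and erythroid markers (7 of 7, median 0.49, adjusted p = 0.0236) were called as well. Each has an adjusted p of 0.906 with an estimated correlation. Adm, the vasoactive peptide adrenomedullin, passed adjusted over the glycolysis and hypoxia list alone (22.2 ± 6.49 and 66.2 ± 22.2 FPKM, limma adjusted p = 0.0447). No other member of these lists passed in that way, and none passed over all genes. The library that stood apart was Atf4WT 1, with levels of -0.705 for the respiratory chain and -0.709 for the tricarboxylic acid cycle. Muscle-rich Atf4AKO 1 was at -0.07 and -0.038, and Atf4WT 1 also had the highest level of epithelial markers (2.42). Without Atf4WT 1 the respiratory chain was called lower (median -0.14, adjusted p = 0.000535), the tricarboxylic acid cycle had a median of -0.10 (adjusted p = 0.232), adipocyte markers 0.06 (adjusted p = 0.645) and glycolysis 0.15 (adjusted p = 0.0559). Without Atf4AKO 2 the respiratory chain (adjusted p = 0.375), the tricarboxylic acid cycle (adjusted p = 0.352) and adipocyte markers (adjusted p = 0.37) were not called, nor were these 3 lists without Atf4AKO 3 (adjusted p = 0.0846, 0.156 and 0.156). Without Atf4AKO 1, proliferation had a median of -0.14 (adjusted p = 0.639), ribosomal proteins 0.06 (adjusted p = 0.122) and erythroid markers 0.19 (adjusted p = 0.207). Without Atf4WT 2 proliferation (adjusted p = 0.123) and erythroid markers (adjusted p = 0.123) were not called, nor was proliferation without Atf4WT 3 (adjusted p = 0.105). With the muscle score covariate, added after the data were seen, the respiratory chain (median 0.01, adjusted p = 0.852), the tricarboxylic acid cycle (0.04, adjusted p = 0.662) and adipocyte markers (0.13, adjusted p = 0.136) were not called. Ribosomal proteins (0.06, adjusted p = 0.126), proliferation (0.09, adjusted p = 0.184) and erythroid markers (0.28, adjusted p = 0.126) were not called with it either, whereas glycolysis was (0.13, adjusted p = 0.0034). Adipocyte markers were called in 10 of 20 alternatives and were also lost with a pseudocount of 0.1 (adjusted p = 0.0502), no filter (0.102), a filter of 2 FPKM (0.0507), quantile normalization (0.217), library weights (0.121) and the epithelial score covariate (0.19). The tricarboxylic acid cycle was called in 9 of 20 alternatives, proliferation in 11 of 19, the respiratory chain in 13 of 20, leaving out its call in the lower direction, erythroid markers in 14 of 20, ribosomal proteins in 15 of 20 and glycolysis in 19 of 20. The ribosomal median was -0.06 after quantile normalization and -0.05 after rescaling to equal sums.

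The libraries did not fall into the 2 groups by overall expression. The first principal component of the log2 values, 50.2% of the variance, put Atf4AKO 1 and 2 at 42.2 and 42.3, and Atf4AKO 3 at -19.9 among the Atf4WT libraries at -36.4, -7.58 and -20.6. Atf4AKO 3 correlated across genes with the 3 Atf4WT libraries at 0.975, 0.984 and 0.985 and with the other Atf4AKO libraries at 0.950 and 0.956. In Atf4AKO 3 the Atf4 value of 114 FPKM was the lowest of the 6.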

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

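Alternatives added after the data were seen are the fit without the 2 muscle-rich knockouts (Atf4AKO 1 and 2) and the 2 covariate fits. The former sets 1 knockout library, assumed to vary like Atf4WT, against 3, so its calls are of that library and not of the genotype. For each change below the cause was not tested, except that leaving libraries out or adding a covariate leaves fewer degrees of freedom. The 2 genes called higher were called in each of the 10 alternatives of pseudocount, filter, scaling, eBayes setting and library weight. The count was 0 without the 2 muscle-rich knockouts, 1 with the muscle score covariate, 1 with the epithelial score covariate, and between 0 and 3 with 1 library left out. Where their calls were lost, the log2 change of Zfp949 stayed between 2.34 and 2.54 and that of Cacna1i between 2.66 and 2.75. With pseudocounts of 0.5 and 0.1 the log2 change of Cacna1i was 3.52 and 5.52. The 0 genes called lower became 1 (Rps19bp1) at an adjusted p under 0.1, and between 0 and 2 with 1 library left out. Atf4 had a log2 change between -1.38 and -1.02 in all 20 alternatives, with adjusted p from 0.0643 to 1. Mthfd2 lay between -0.48 and 0.23 and was never called (lowest adjusted p 0.669). Its sign reversed to 0.0216 with quantile normalization, and it lay between -0.25 and 0.23 with 1 library left out. Rescaling to equal sums (TPM) moved the median of all genes by -0.13 (log2), so Atf4 at -1.29 and Mthfd2 at -0.14 under it are to be read against that shift.

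The 13 lists called higher became 8 with quantile normalization, 6 with the muscle score covariate, 0 with an estimated correlation and 0 with fry (smallest adjusted p 0.659 and 0.157), and 10 to 16 with 1 library left out. The 2 lists called lower became 1 with a pseudocount of 0.1, with no filter, with quantile normalization, with TPM rescaling, with library weights, with the muscle score covariate and with the epithelial score covariate. They became 4 without the 2 muscle-rich knockouts, 0 with an estimated correlation, 0 with fry, and 1 to 4 with 1 library left out. List tests that reversed had medians of -0.0637 (quantile normalization) and 0.00468 (without the 2 muscle-rich knockouts) for ribosomal proteins, -0.01397 for erythroid, -0.19 for proliferation and -1.84 for muscle markers (all without those knockouts), and -0.0377 for muscle markers with the muscle score covariate. That covariate is the level of the muscle list itself, which removes the list's change and its call by construction, as the epithelial one does for the epithelial list. Medians also changed sign, with the list tests in their former direction, for ribosomal proteins (-0.05) and thermogenic genes (-0.02) with TPM rescaling and for epithelial markers (0.10) without those knockouts. So did medians of lists that were not called: the serine, the amino acid and the thermogenic list under other alternatives. With 1 library left out the respiratory chain lay between -0.14 (without Atf4WT 1, adjusted p = 0.000535) and 0.40, the tricarboxylic acid cycle between -0.10 (without Atf4WT 1) and 0.45, and proliferation between -0.14 (without Atf4AKO 1) and 0.43. The immediate early, inflammatory, matrix and synthetase lists were called in each of 20 alternatives of values, filter, fit and libraries. Of 338 values of the other named genes under alternatives 328 kept direction and side of the threshold and 10 lost a call. These genes were picked by their p in the same data, so their direction was nearly bound to hold. Only Cacna1i and Zfp949 had a call to lose, and all 10 losses were theirs.

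Replicate pairing stays open. Same-numbered libraries deviated from group means with correlations across genes of 0.08, 0.40 and 0.07. Atf4WT 1 and Atf4AKO 3 correlated best with each other (0.19), and the other libraries with their own number. With a replicate block 0 genes were called higher and 0 lower, and 14 lists were called higher and 2 lower. Absolute depth is unknown, so values near 0 have no counting interval.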

Other observations

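Several other gene groups held members whose groups did not overlap, though none of these lists was called and no member passed over all genes. Values are FPKM in Atf4WT and Atf4AKO (mean ± SD, n = 3 each). Among 18 circadian clock genes 4 lay above and 2 below in all Atf4AKO libraries (camera adjusted p = 0.743), with the repressor gene Nr1d1 at 13.5 ± 4.53 and 53.0 ± 28.0, Nfil3 at 82.0 ± 6.001 and 118 ± 7.59, and Dbp at 1.96 ± 0.713 and 4.32 ± 1.38. Among 12 genes of UCP1-independent energy dissipation (camera adjusted p = 0.084) Gamt, of creatine synthesis, passed adjusted over the list alone (limma adjusted p = 0.00433). In cholesterol synthesis 4 of 19 genes lay below in all Atf4AKO libraries (camera adjusted p = 0.715), among them Msmo1 at 13.0 ± 0.990 and 8.70 ± 1.6 and Hmgcs1 at 24.4 ± 1.33 and 17.1 ± 2.92. In fatty acid and triglyceride synthesis (camera adjusted p = 0.289) Acly was 33.3 ± 5.32 and 55.2 ± 11.9, whereas Srebf1 was 15.02 ± 2.47 and 10.6 ± 2.35. In fatty acid oxidation (camera adjusted p = 0.761) Ehhadh, a peroxisomal enzyme, was 1266 ± 151.4 and 563 ± 405.3.

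The remaining lists were not called either. Camera adjusted p was 0.289 for lipolysis and lipid droplets, 0.8 for endoplasmic reticulum chaperones, 0.864 for mitochondrial chaperones and proteases, 0.715 for antioxidant and glutathione genes, 0.683 for interferon response genes, 0.8 for T and NK cell markers, and 0.352 for B cell and lymph node markers. It was 0.117 for granulocyte and mast cell markers, 0.514 for endothelial markers, 0.252 for smooth muscle and pericyte markers and 0.514 for Schwann cell and nerve markers. Xist was under 0.015 FPKM and Ddx3y between 32.5 and 56.4 FPKM in all 6 libraries. The ribosomal RNA precursor gene Rn45s was 1396 FPKM in Atf4WT 2 and between 102 and 205 FPKM in the other libraries.

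The tests that follow were chosen after the values were seen, except the counts over other splits of the libraries. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave 2 genes higher, against at most 1 in a direction in the others, and 0 genes lower. It gave 13 lists higher and 2 lower, against at most 16 in a direction in the others. Counting the real one, 1 split gave as many higher genes as the real split, 10 gave as many lower genes, 4 gave as many higher lists and 10 as many lower lists. Parting Atf4AKO 1 and 2 with Atf4WT 2 from the others gave 1300 genes with an unadjusted p under 0.05, and parting Atf4AKO 1 and 2 with Atf4WT 1 gave 1339, against 1276 for the real split, so the libraries have a structure of their own.

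Genes beside the engineered loci may have changed through the loci themselves: of 5 tested genes within 100 kb of Atf4, Cacna1i and Rps19bp1 were among the 10 of smallest p (exact hypergeometric p = 5.5e-06), and 1 lay above and 2 below in every Atf4AKO library (exact binomial p = 0.349 for above and 0.0346 for either direction). The first of these tests restates the ranks that prompted it, so a local effect of the recombined allele stays open, as does read-through past the end of Atf4 into Cacna1i on the same strand, with the gene just upstream, Mief1, at -0.23 (SE 0.10). Loss of the ATF4 protein as the cause at these genes also stays open, and the 4 ATF4-related lists cannot decide it, since they hold other genes. Of their 79 members 15 lay below in all Atf4AKO libraries (19.0% against 8.34% of all genes, exact binomial p = 0.00207). Of these 8 came from the synthetase list, already called lower in the same data, and 3, 2 and 2 from the serine, stress response and amino acid lists. Of the 11 members that lay above (13.9%, against 8.21% of all genes) 0 came from the synthetase list and 2, 7 and 2 from those other lists. Near Adipoq, whose promoter drives Cre, 3 of 4 tested genes within 100 kb were higher in every Atf4AKO library (exact binomial p = 0.00208, and 0.0158 for either direction). Eif4a2 was 1.33 times, Rfc4 2.05 times and St6gal1 1.501 times as high by mean FPKM. Extra gene copies on a transgene holding that region would give this, but the labels do not say what the transgene holds. Adipoq itself, not counted, was 1.26 times as high, and its groups overlapped. Snora81, the remaining tested gene, lies within Eif4a2, and Rfc4 overlaps the end of Eif4a2, so these are not separate genes. Of the 4, 0 were among the 10 genes of smallest p. The binomial p-values treat neighbours, and list members that move together, as independent. Around Zfp949, on chromosome 9, 0 of 3 tested genes within 100 kb were separated. That window does not reach a longer stretch inherited with Cre, which was not tested.

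Skeletal muscle transcripts may come from muscle left on some pads. The 20 muscle members, fixed as markers beforehand, had nearly the same profile in the 3 libraries of highest level (Atf4AKO 2, Atf4AKO 1 and Atf4WT 2), with a smallest correlation across members of 0.972, but all genes correlated at 0.926 to 0.985 between any 2 libraries, so this does not decide the source; among these transcripts were Acta1 at 1467, 604.8 and 170.2 FPKM and Ckm at 1030, 356.7 and 99.5 FPKM in these libraries. Of these markers Atp2a1 and Ryr1 also stand in the list of energy dissipation and Des in that of smooth muscle. An effect of Atf4 loss on muscle genes in every knockout would have to leave out Atf4AKO 3, which lay at -3.80 (log2) relative to the highest Atf4WT library, but 1 library does not exclude it.

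The higher immediate early, inflammatory, macrophage and matrix lists were weighed against tissue composition. RNA from skeletal muscle as a source of part of their rise stays open. As the only source it is at odds with the levels of the immediate early and inflammatory lists. Atf4AKO 3, lowest in muscle markers (-2.70), lay at 0.09 and 0.05, above every Atf4WT library. Atf4WT 2, at 1.09 for muscle markers, lay at -0.29 and -0.42. Each of these points rests on 1 library. With the muscle score covariate all 4 lists were still called higher (medians 0.41, 0.67, 0.88 and 0.65, largest camera adjusted p 0.000105). That call cannot decide whether muscle RNA had a part, because the same list test called 11 to 23 lists in splits that mixed the groups. A covariate on the log2 scale also need not remove RNA that adds to FPKM. The macrophage median was 1.36 without the covariate, and without it no list was called by camera with an estimated correlation (smallest adjusted p 0.659). With Atf4AKO 3 as the only knockout library the macrophage list was not called (median 0.22, adjusted p 0.0582), which 1 library cannot decide. A lower share of adipocytes stays open: macrophage markers parted from endothelial markers by 1.02 (SE 0.80 over libraries) and from smooth muscle markers by 1.26 (SE 0.81), which is within 2 standard errors. Lyve1 (log2 change 1.71) stands in both the macrophage and the endothelial list, which narrows their gap. Adipocyte markers had a median change of 0.24 and smooth muscle markers of -0.12, each opposite to what a lower share would give. The adipocyte list was called in only 10 of 20 alternatives, and the smooth muscle list was not called. Loss of Atf4 in adipocytes, Cre itself, handling before freezing and differences between animals were not tested and also stay open.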
